A study of Sus scrofa with 2 samples.

How the data were processed

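Corneoscleral wedges of 2 pigs, digested with papain per the labels, were profiled with droplet single-cell RNA sequencing (10x Chromium 3' chemistry). Per the labels, the submitters aligned reads and counted molecules with Cell Ranger 3.0.2 on the pig genome build Sscrofa11.1. The deposited matrix holds raw UMI counts, integers that count distinct transcript molecules per gene and cell, for 25880 genes, and the columns were matched to the 2 samples with 0 columns left over. The 2 samples form 1 group, with animal 6 as replicate 1 and animal 9 as replicate 2. The files give gene names only, so no coordinates are given. Of the genes, 8147 are given only as an Ensembl identifier, 936 of which were given a symbol here, and 7633 had no count in any cell.

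Animal 6 held 2034 cells with 980 to 131483 UMIs each, and animal 9 4675 cells with 975 to 238773. Cells with at least 500 genes and a mitochondrial share up to 20% were kept. The gene minimum removed no cell, as the lowest count of genes was 602, and the mitochondrial limit removed 38 and 149 cells. Doublets were called per animal with Scrublet at an expected 6%, which removed 23 and 69 cells. Cells were clustered with scanpy 1.11.5 under Python 3.11.15 on 2000 variable genes, leaving out the genes of the fixed lists, scaled within each animal, with 30 principal components, 15 neighbours and the Leiden method at resolution 1.0. Supporting packages were scikit-learn 1.9.0, igraph 0.11.9, SciPy 1.17.1, numpy 2.4.6 and pandas 2.3.3.

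Clusters were named from 25 sets of marker genes. A marker counted as raised at 2-fold over the mean of the other clusters, with a UMI in at least 10% of cells and a highest level of at least 20 CPM, where CPM is a gene's UMIs scaled to a common total. A name needed 3 raised markers. The 10 leading genes, ranked with a pseudocount of 20 CPM, could not hold more markers of an unrelated class. Stromal clusters needed a lead of 0.5 in z score between trabecular and fibroblast markers. Elsewhere the class with the most raised markers gave the name. Between related classes, such as pericyte and ciliary muscle or blood and lymphatic endothelium, the higher mean marker level decided, with no lead required. Names end in "-like" because they rest on markers alone. Marker sets, 14 gene lists with 329 genes (312 in the matrix), the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined.

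Raw UMIs were summed per class and animal, and classes with at least 20 cells in each animal entered 1 edgeR quasi-likelihood fit (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling, filterByExpr at its default minimum count of 10 and the animal as a block, since every class comes from the same animals. The fit had 10 classes, 9281 genes, 9 residual degrees of freedom and a common dispersion of 0.0605. Blood vascular endothelial-like cells numbered 19 in animal 6, so comparisons with them used a fit of classes with at least 10 cells, chosen after seeing the data. A class was compared with the mean of the logarithms of the other classes, or with 1 other class. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and again over each list alone. With the animal as a block, they rest on how class differences vary between 2 animals, with a spread shared over all classes of the fit. They do not measure the spread of the compared class alone and cannot stand for pigs in general. Whole lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation. CPM of class comparisons are TMM-scaled, and CPM of single clusters and of the ciliary muscle comparison use total UMIs. Standard errors of log2 differences are the difference over the square root of F.

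Named genes are, for each list, up to 4 members with the largest absolute log2 difference among those past the threshold with an absolute log2 difference of at least 1, the same sign in both animals and at least 10 CPM in the higher class, up to 30 per comparison, plus 18 genes always given. Where every UMI count of 1 side was 0, the fold is a lower bound from 3 counts over the group, and for a few UMIs the pooled ratio is given with its exact counting interval. Shares carry exact binomial (Clopper-Pearson) 95% intervals, and single-cluster levels exact Poisson 95% intervals; both cover counting error only. The correlation between animals used log2 of CPM with a pseudocount of 1. Values for 1 animal alone are differences of log2 CPM with a pseudocount of 1, which is another estimator than the fit, and their moves are counted from the mean of both animals on that scale.

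The fit was tested on simulated negative binomial counts drawn from the mean profile and library sizes of the class sums, with known genes changed in 1 class. For genes changed 4-fold, 94% of higher and 86% of lower genes were recovered in the comparison of trabecular meshwork-like cells with the other classes, 90% and 58% against stromal fibroblast-like cells, 90% and 46% for blood vascular endothelial-like cells against the other classes, and 28% and 74% between the endothelial classes. Unchanged genes called numbered 8 of 7878, 7 of 7892, 2 of 7951 and 6 of 7949. Apart from the changed genes every simulated class had the same profile, with the same dispersion for all genes and no difference between animals. The real classes differ in more genes, so these recoveries and false calls hold for the simulated setting only. Between the endothelial classes the change was placed in the blood vascular class alone.

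The alternatives were DESeq2 size factors, the DESeq2 test (DESeq2 1.42.0), no filter on low counts, no replicate block, leaving out each animal, cells with at least 1000 genes, a mitochondrial share up to 10%, Leiden resolutions 0.5 and 2.0, all variable genes in the clustering, doublets kept, and at least 50 cells per class. Chosen after seeing the data were genes scaled over both animals for the comparisons of classes, clusters named despite their leading genes, and stromal clusters with close scores taken as trabecular. A gene counts as reversed when its sign differs and at least 1 of both values is past the threshold. Ciliary muscle-like and corneal endothelial-like cells had too few cells in animal 6 for a test. The planned test of clusters within the trabecular meshwork-like class was not run because each cluster lay almost wholly in 1 animal, and a comparison of 2 stromal clusters found with both animals scaled together took its place.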

Results

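Single cells were profiled from the corneoscleral wedge of the pig eye, the strip where cornea meets sclera that holds the trabecular meshwork, the porous tissue through which aqueous humor leaves the eye. The series is the pig part of a survey of outflow tissues in several species used to study glaucoma. The 2 samples form 1 group of 2 animals, numbered 6 and 9 in the labels and called animal 6 and animal 9 here. No groups of animals could be compared, so every comparison is between classes of cells taken from the same animals. Animal 6 gave 2034 barcodes and 31293869 UMIs, with a median of 10685 UMIs and 2625.5 genes per cell. Animal 9 gave 4675 barcodes and 65212577 UMIs, with medians of 9576 UMIs and 2783 genes. After filtering, 1973 cells of animal 6 and 4457 cells of animal 9 were analysed. Levels are CPM, a gene's UMIs in the summed cells of a class relative to the class's total UMIs, TMM-scaled in comparisons of classes. They are given as the mean ± SD over the animals (n = 2). Genes are named by the symbols in the matrix, except AQP1 (ENSSSCG00000033190), CFB (ENSSSCG00000024914), EPDR1 (ENSSSCG00000020963), KLF4 (ENSSSCG00000005437), TGFB1 (ENSSSCG00000003017) and TNXB (ENSSSCG00000023611), which it gives by these identifiers.

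Trabecular meshwork-like cells made up 15.7% ± 2.13 of the analysed cells (SD, n = 2), and stromal fibroblast-like cells 6.75% ± 0.227. The trabecular meshwork-like share was 14.2% (281 cells, exact binomial 95% interval 12.7 to 15.9%) in animal 6 and 17.2% (769 cells, 16.1 to 18.4%) in animal 9. Surface epithelial-like cells of the cornea, limbus and conjunctiva took 46.4% of animal 6 and 15.7% of animal 9, and macrophage-like cells 3.09% and 12.4%. Endothelial classes were small, with blood vascular endothelial-like cells at 0.963% (19 cells) and 1.44% (64 cells), and lymphatic or Schlemm canal endothelial-like cells at 1.22% (24 cells) and 1.17% (52 cells). Schlemm canal is the vessel that collects aqueous humor behind the meshwork. Pericyte-like cells held 2.53% and 1.26%, non-myelinating Schwann-like cells 1.37% and 1.23%, pigment cell-like cells 1.27% and 0.875%, T or NK cell-like cells 1.37% and 2.92%, and cycling cells 4.97% and 2.22%. Ciliary muscle-like cells numbered 4 and 28, and corneal endothelial-like cells 2 and 24. No test of shares was possible with 1 group and the intervals cover counting error only.

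**Figure D1:**
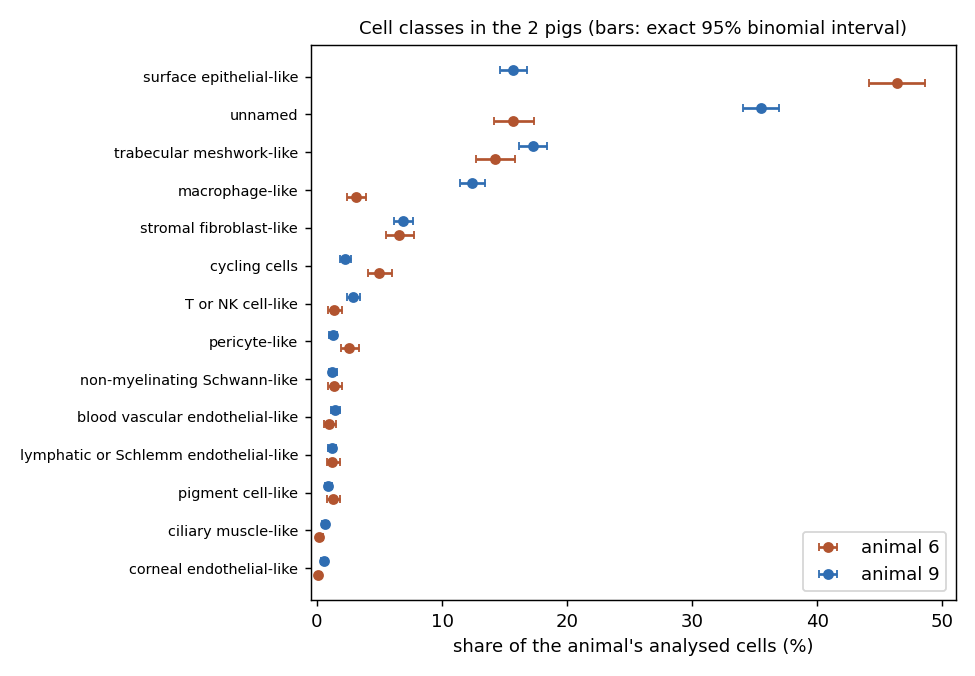
Share of analysed cells (percent, x axis) in each class (y axis) for animal 6 and animal 9, with exact binomial 95% intervals as error bars. The trabecular meshwork-like share was 14.2% and 17.2%, while the surface epithelial-like share was 46.4% and 15.7%.

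Clusters without a name held 15.7% of the cells of animal 6 and 35.5% of those of animal 9. The largest part by cells of both animals together was 2 stromal clusters of 713 cells that scored close on trabecular and fibroblast markers. It made up 0.405% of animal 6 and 15.8% of animal 9. A stromal cluster of 379 cells led by CHGB, CCK and RSPO3 made up 0.507% and 8.28%, and stayed unnamed because its leading genes held more corneal endothelial than trabecular markers. Epithelial clusters led by genes on the neutrophil or keratocyte marker lists, such as S100A8, S100A9 and ALDH3A1, held 449 and 287 cells. Those with neutrophil-list genes took 10.3% of animal 6, its largest unnamed part, and 5.52% of animal 9. Of the 31 clusters, 19 took at least 95% of their cells from 1 animal, so the trabecular meshwork-like class rested on cluster 6 in animal 6 and on clusters 18, 20 and 22 in animal 9. With genes scaled over both animals, 6 of 28 clusters did.

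How alike the animals were differed by class. Across 9378 genes, which are not independent replicates, the Pearson correlation of log2 CPM between the animals was 0.968 for surface epithelial-like, 0.953 for trabecular meshwork-like and 0.927 for stromal fibroblast-like cells. It was 0.851 for blood vascular and 0.856 for lymphatic or Schlemm canal endothelial-like cells, and lowest, at 0.743, for non-myelinating Schwann-like cells. Between different classes of different animals the median was 0.587 and the highest 0.914. UMIs of S100A12 were widespread: the gene, at 54780 ± 8208 CPM in surface epithelial-like cells, had a UMI in 96.0% of all cells of animal 6 and 85.9% of those of animal 9, and stood at 1290 ± 1320 CPM in blood vascular endothelial-like cells. Whether these are free RNA was not tested.

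Trabecular meshwork-like cells were compared with the other 9 classes to describe the transcripts of the tissue the series set out to profile. They carried a broad set of matrix genes: 36 of the 40 structural matrix genes tested were higher than in the mean of the other classes and none was lower. FBN2, a fibrillin of elastic microfibrils, stood at 48.8 ± 7.17 CPM against 3.79 ± 2.15 in pericyte-like cells, the class with the next highest level. FMOD, a collagen-binding proteoglycan, stood at 440.2 ± 88.7 CPM against 116 ± 143 in pigment cell-like cells. For MFAP2 (223 ± 72.5 against 179 ± 20.7 CPM) and COL1A2 (7707 ± 2978 against 9162 ± 7779 CPM) stromal fibroblast-like cells were close or higher. Among genes linked to glaucoma and eye pressure, 23 of 42 were higher and 1, PAX6, was lower. COL8A2, a network-forming collagen, stood at 675 ± 224 CPM against 29.5 ± 41.7 in pericyte-like cells, a log2 difference of 6.48 ± 0.342 (SE) from the mean of the classes with an edgeR adjusted p of 1.03e-10. LMX1B, a transcription factor of anterior eye development, stood at 78.1 ± 11.2 CPM against 17.4 ± 3.34 in stromal fibroblast-like cells. The next class is the highest of the others in the fit. Ciliary muscle-like cells, outside it, held LMX1B at 176 CPM and CHRM2 at 67.7 CPM in animal 9. Corneal endothelial-like cells lay outside it too, so the level of COL8A2 there was not compared. Blood vascular endothelial-like cells, with 19 cells in animal 6, were also outside this fit. MYOC, which encodes the secreted protein myocilin, stood at 80.5 ± 43.2 CPM and its log2 difference was 4.71 ± 0.499 (edgeR adjusted p = 5.32e-07). Of the MYOC UMIs of animal 9, 8.33% (414 of 4972) lay in this class and 88.8% in unnamed clusters, against 96.9% and 0.625% in animal 6. CYP1B1, a cytochrome P450, was at 342 ± 116 CPM against 196 ± 79.4 in stromal fibroblast-like cells, and LTBP2, a microfibril protein, at 55.1 ± 25.5 against 39.9 ± 56.5 in pigment cell-like cells, both past the threshold against the mean of the classes.

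Receptors and signalling genes differed as well. PTGFR, the receptor targeted by prostaglandin eye drops, stood at 46.8 ± 4.35 CPM in trabecular meshwork-like cells, but at 85.6 ± 7.57 in pigment cell-like cells. CHRM2, a muscarinic receptor, was at 42.3 ± 4.0 CPM against 15.1 ± 13.9 in pericyte-like cells. In the list of drug targets 8 of 14 genes were higher and 2 lower, one of them EDNRB, an endothelin receptor, at 4.62 ± 1.58 CPM against 1150 ± 463 in pigment cell-like cells (edgeR adjusted p = 0.005). ANGPT1, a ligand of the TEK receptor, was at 29.6 ± 10.8 CPM and ANGPT2 at 35.1 ± 20.3, while pericyte-like cells held 61.4 ± 3.36 and 128 ± 8.27. TEK itself was at 0.362 ± 0.512 CPM (edgeR adjusted p = 0.968). SFRP1, a secreted WNT antagonist, stood at 686 ± 342 CPM against 276 ± 156 in pigment cell-like cells, and 15 of 23 genes of TGF-beta, BMP and WNT signalling were higher with 1 lower. The water channel AQP1 was at 207 ± 97.5 CPM, below the 338 ± 403 of lymphatic or Schlemm canal endothelial-like cells. Blood vascular endothelial-like cells, outside this fit, held still more AQP1 in the fit that took them in. Of 15 ion and water transport genes, 4 were higher and 1 lower. CAV1 (65.5 ± 72.5 CPM, edgeR adjusted p = 0.172) and NR3C1, the glucocorticoid receptor (102 ± 6.51 CPM, 0.865), did not pass the test. FOXC1 with 102 UMIs in the class, SVEP1 with 20, ADRA2A with 11, NOS3 with 3 and CA2 with 70 lay under the count filter and were not tested.

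The remaining lists were counted in the same fit, which held no blood vascular endothelial-like cells. Higher genes numbered 14 of 19 for matrix turnover and cross-linking (LOX at 63.4 ± 0.440 CPM, MMP2 at 409 ± 5.38), 12 of 22 for contractility regulators (MYLK at 155 ± 40.6), 9 of 12 for mechanosensing and YAP targets, 8 of 14 for angiopoietin and VEGF signalling (NRP2 at 482 ± 17.8), and 7 of 10 for complement (C1R at 952 ± 255, with 3002 ± 435 in stromal fibroblast-like cells). They numbered 8 of 17 for antioxidant genes, 7 of 13 for phagocytosis and lysosome (APOE at 3596 ± 1603) and 8 of 18 for early response genes. Outside the mitochondrial list the 10 lower genes were PLAU, PDLIM3, RHOA, ROCK1, NOTCH1, PDGFB, SLC4A7, TGFB1, PAX6 and EDNRB, named after their values were seen except EDNRB. Adjusted over the list alone, higher genes numbered 16 for matrix turnover, 11 for mechanosensing, 9 for angiopoietin and VEGF signalling, 17 for TGF-beta, BMP and WNT signalling, 9 for antioxidant and 10 for early response genes, and the counts of the other lists stayed as they were. Over all 9281 genes tested with edgeR, 2079 were higher and 525 lower. In camera's set test with a preset correlation, the structural matrix (adjusted p = 4.33e-21) and glaucoma lists (5.69e-05) stood above other genes and held with an estimated correlation (adjusted p = 0.0487 and 0.028). Matrix turnover (1.06e-04), TGF-beta, BMP and WNT signalling (4.52e-06), complement (4.53e-05), mechanosensing (7.19e-04), phagocytosis (0.0137), angiopoietin and VEGF signalling (0.0163), early response (0.0363) and contractility (0.0444) passed with the preset correlation. With an estimated correlation their adjusted p was 0.116, 0.0855, 0.116, 0.0516, 0.116, 0.116, 0.417 and 0.232 in that order. Drug targets, antioxidant genes (both adjusted p = 0.113) and ion and water transport (0.538) did not pass.

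The mitochondrially encoded list was lower as a set in trabecular meshwork-like cells with the preset correlation (camera adjusted p = 0.00875, and 0.353 with an estimated correlation), with 1 of its 13 genes, ND6, past the edgeR threshold and named after its value was seen. The median mitochondrial share was 6.29% and 6.00% per animal in this class. All 36 named genes past the threshold had the same sign in each animal alone. The naming rule required this of every gene but those always given, so it says little about agreement. Of the 36 genes, 16 moved by over 1.5-fold from the mean of both animals when either was left out. In animal 6 alone and animal 9 alone the log2 difference was 6.24 and 3.01 for MYOC, 8.40 and 5.44 for COL8A2, 5.26 and 2.23 for LTBP2, 7.15 and 4.13 for FMOD, and -1.59 and -3.69 for EDNRB. The class rested on cluster 6 in animal 6 and on clusters 18, 20 and 22 in animal 9. The SDs, these values and the tests cannot tell a different mix of cells from a difference between the animals. Fitted differences from the mean of 9 classes depend on the prior count wherever some class is near 0, so the levels carry the size.

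**Figure D2:**
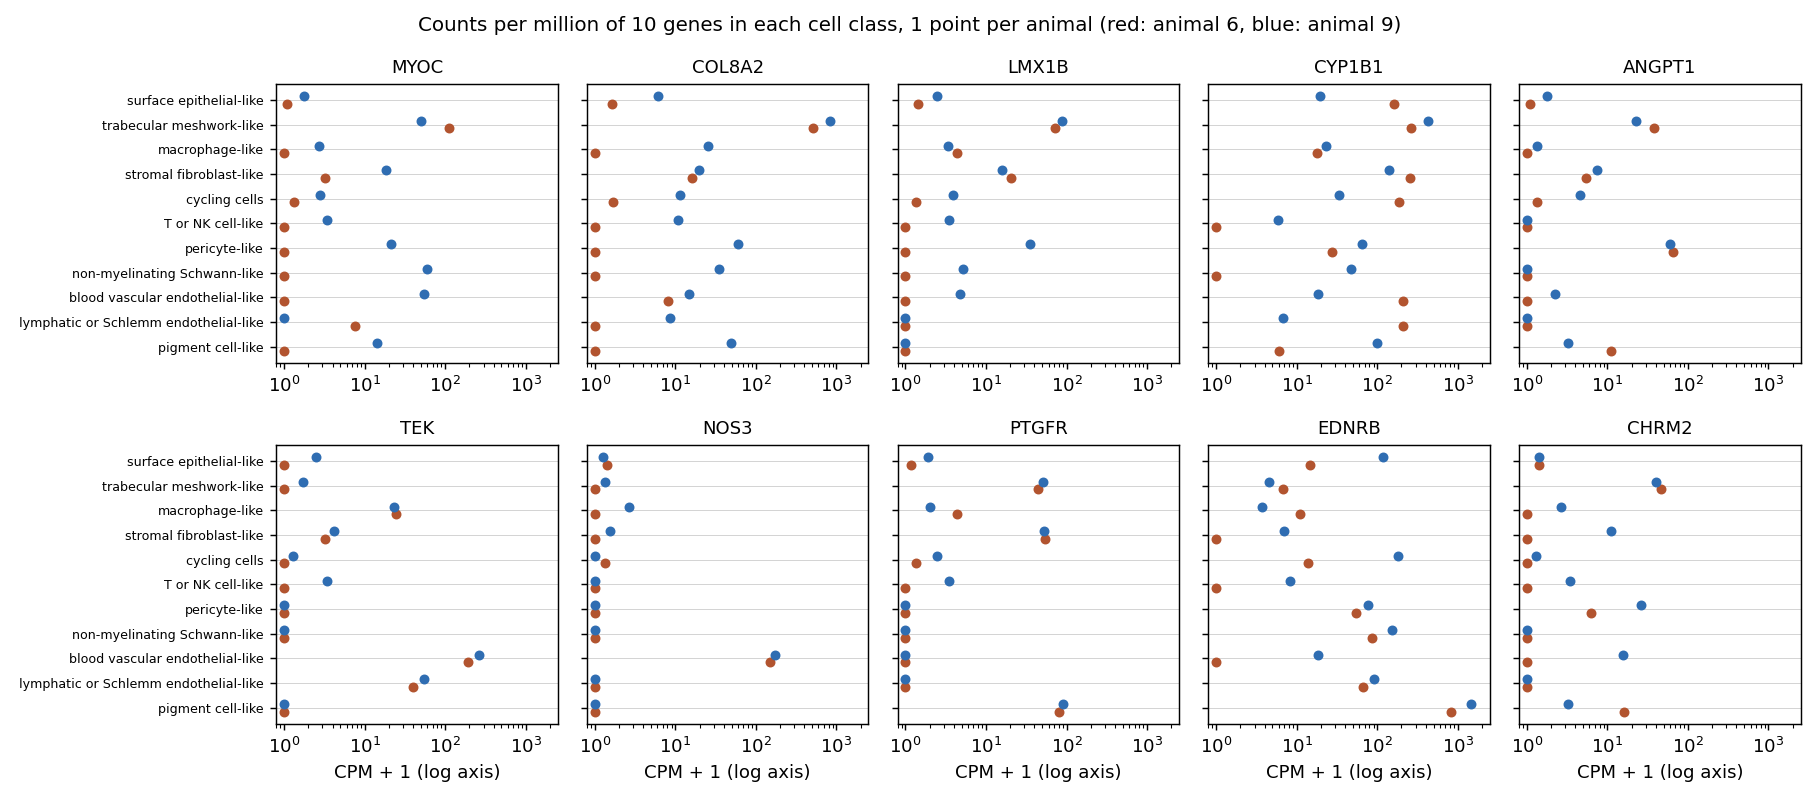
CPM + 1 (log axis) of 10 named genes in 11 classes, with a point for each animal. In the fit of 11 classes COL8A2 stood at a mean of 672 CPM in trabecular meshwork-like cells against 29.4 in the next class, and NOS3 at 160.3 in blood vascular endothelial-like cells. The fit leaves out corneal endothelial-like and ciliary muscle-like cells.

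Trabecular meshwork-like cells were next set against stromal fibroblast-like cells, the matrix-producing cells beside them. FBN2 had 507 UMIs in the former and 0 in the latter, at least 41.2-fold higher, and COL8A2 stood at 675 ± 224 against 17.1 ± 2.43 CPM (log2 difference 5.83 ± 0.708, edgeR adjusted p = 1.72e-05). MYLK, the myosin light chain kinase, stood at 155 ± 40.6 against 3.52 ± 1.87 CPM, NRP2 at 482 ± 17.8 against 11.6 ± 4.04, SFRP1 at 686 ± 342 against 18.6 ± 13.9, and APOE at 3596 ± 1603 against 440.4 ± 175. In the other direction, complement C4A stood at 31.5 ± 2.05 against 1560.0 ± 356 CPM (log2 difference -5.73 ± 0.633, edgeR adjusted p = 8.28e-06), fibronectin FN1 at 21.6 ± 7.98 against 676 ± 187, TNXB at 15.4 ± 3.60 against 680 ± 371, and the protease PLAU at 11.12 ± 4.59 against 501 ± 134. MYOC stood at 80.5 ± 43.2 against 9.96 ± 10.98 CPM, a log2 difference of 2.96 ± 0.758 (edgeR adjusted p = 0.0129) that was 5.13 in animal 6 alone and 1.45 in animal 9 alone.

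By list, 9 of 40 structural matrix genes were higher in the trabecular meshwork-like class (COL4A2 at 108 ± 1.02 against 4.34 ± 0.0668 CPM) and 12 lower. Of 42 glaucoma genes 9 were higher, among them COL11A1, THSD7A (99.6 ± 17.1 against 3.22 ± 4.56), LMX1B and LTBP2, and 2 lower, CAV1 (65.5 ± 72.5 against 268 ± 0.277) and GAS7. ANGPT2 had 2 UMIs in stromal fibroblast-like cells and a pooled ratio of 53.5 (counting interval 14.7 to 443). Matrix turnover had 0 of 19 genes higher and 4 lower (PLAU, HAS1, PLAT and LOX), and complement 1 of 10 higher (CLU) and 2 lower (C2 and C4A). TGF-beta, BMP and WNT signalling had 5 of 23 higher (ID1, ID3, SFRP1, SFRP2 and TGFB3) and 4 lower (INHBA, LTBP1, TGFBR2 and WIF1). Contractility regulators had 4 of 22 higher (CNN2, MYLK, PPP1R14A and TPM1) and 2 lower (PDLIM3 and RHOA). Drug targets had 3 of 14 higher (PTGER2, CHRM2 and FKBP5) and 0 lower, and angiopoietin and VEGF signalling 4 of 14 higher (ANGPT2, NRP1, NRP2 and TIE1) and 1 lower (S1PR1). Among the rest, ion and water transport had 2 of 15 higher (ATP1B1 and CLCN3). Antioxidant genes gave 2 of 17 higher (MT3 and GSTM3) and 1 lower (SOD2), and mechanosensing 1 of 12 higher (AJUBA) and 1 lower (KLF4). Phagocytosis had 1 of 13 higher (APOE) and 1 lower (AXL), early response 0 of 18 higher and 1 lower (HSPH1), and the mitochondrially encoded list 0 of 13 either way. AJUBA, CLCN3, CNN2, FKBP5, GAS7, GSTM3, HSPH1, ID1, ID3, INHBA, KLF4, LOX, LTBP1, NRP1, PPP1R14A, RHOA, SOD2, AXL and TGFBR2 were named after their values were seen. Values for CYP1B1 (342 ± 116 against 196 ± 79.4 CPM, edgeR adjusted p = 0.596), ANGPT1 (29.6 ± 10.8 against 5.42 ± 1.45, 0.0625) and PTGFR (46.8 ± 4.35 against 52.4 ± 0.422, 0.919) did not pass the test, nor did TEK, NR3C1 and EDNRB.

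Over all 9281 genes 584 were higher and 471 lower by edgeR. Adjusted over the list alone, the structural matrix had 12 higher and 14 lower, the glaucoma list 10 and 4, matrix turnover 2 and 8, contractility 7 and 2, and drug targets 4 and 2. Angiopoietin and VEGF signalling had 6 and 1, TGF-beta, BMP and WNT signalling 6 and 5, complement 2 and 5, antioxidant 3 and 1, phagocytosis 2 and 1, and early response 0 and 0. In camera's test only matrix turnover passed, as lower (adjusted p = 0.0178 with the preset correlation, adjusted p = 0.806 with an estimated correlation). Of the 34 named genes past the threshold, 34 kept their sign in each animal alone and 11 moved by over 1.5-fold. The naming rule required the same sign of all but the genes always given. In animal 6 alone and animal 9 alone the log2 difference was 6.82 and 3.57 for THSD7A, 5.62 and 0.91 for SFRP2, 5.53 and 1.85 for CHRM2, 5.09 and 1.72 for ATP1B1, 3.29 and 1.70 for LTBP2, and -1.19 and -4.14 for CAV1. Here too each class came from different clusters in each animal, so the mix of cells may differ. The fit without the animal as a block called 21 list genes higher in place of 40, and MYOC, LTBP2, LMX1B, APOE, CHRM2, SFRP2 and CAV1 were among those no longer past the threshold.

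Stromal clusters of animal 9 differed in level, but these values have no replicate because each cluster lay almost wholly in 1 animal. MYOC stood at 72.5 CPM in cluster 18 and 12.2 CPM in cluster 20, both trabecular meshwork-like, and at 324 CPM (exact Poisson 95% interval 254 to 408) in cluster 22. COL8A2 ran the other way, at 268 CPM in cluster 18 and 1270.0 CPM in cluster 20. APOE stood at 4953 CPM in cluster 18 and 137 CPM in cluster 20. Stromal fibroblast-like cells of animal 9, cluster 26, held MYOC at 16.3 CPM and COL8A2 at 17.3 CPM.

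**Figure D3:**
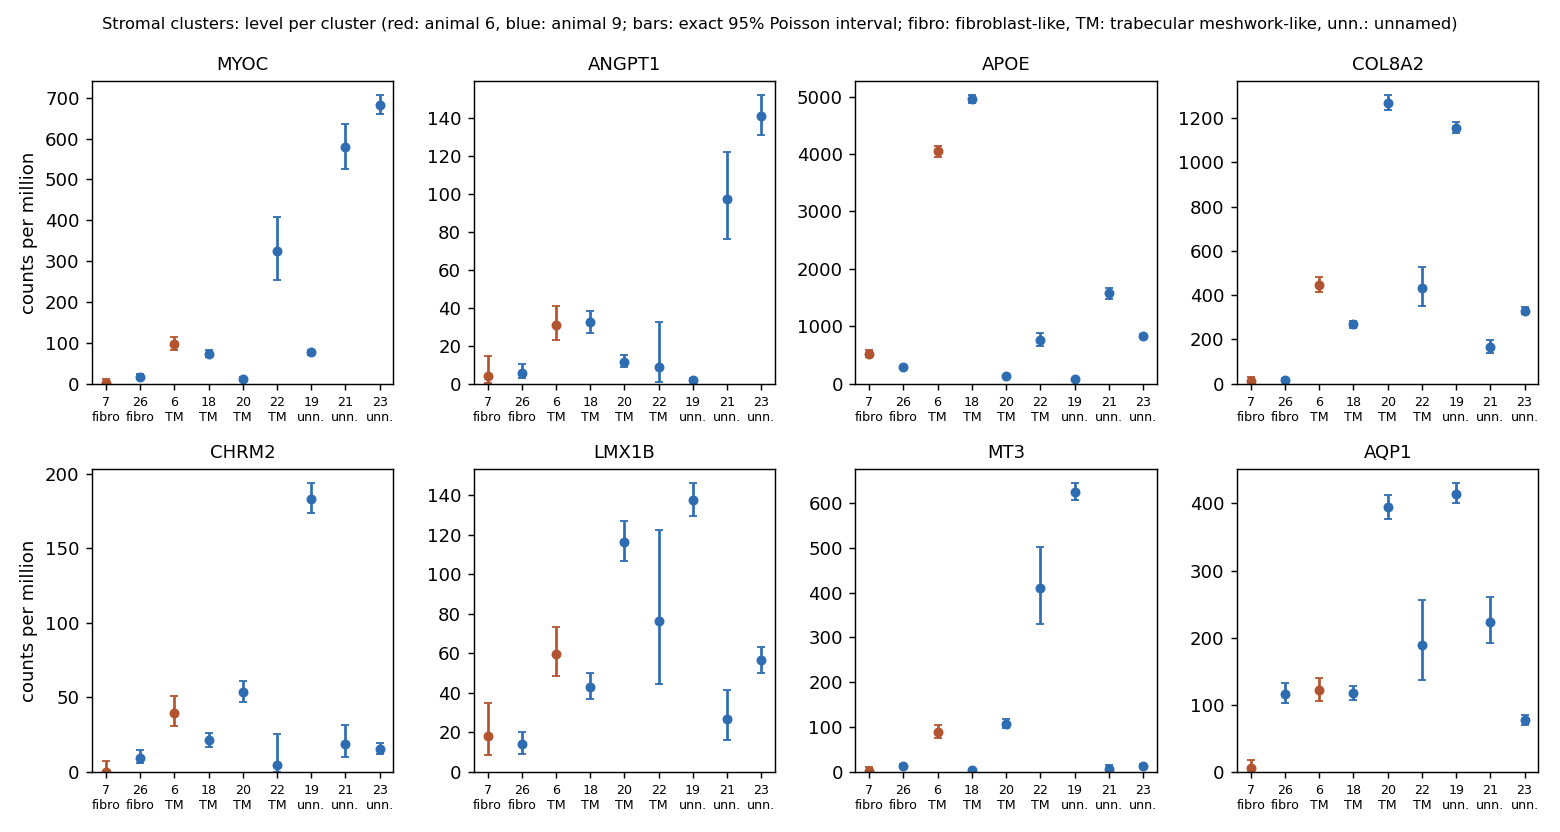
CPM of 8 named genes in each stromal cluster with exact Poisson 95% intervals, which cover counting error only. In animal 9 MYOC lay at 12.2 CPM in cluster 20 and 72.5 CPM in cluster 18, and COL8A2 at 1270.0 CPM and 268 CPM.

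To test such a difference over both animals, 2 stromal clusters of a clustering with genes scaled over both animals were compared. The comparison was chosen after seeing the data. They were the 2 largest with at least 20 cells in each animal and a higher z score for trabecular than for fibroblast markers. Both therefore lean trabecular by choice. The first, led by RARRES1, held 208 cells of animal 6 and 572 of animal 9 and was trabecular meshwork-like, and the second, led by CCK, RSPO3 and CHGB, held 35 and 377 and had no name. The second scored higher on trabecular minus fibroblast markers (z score difference 1.73 against 0.605). APOE, a lipid carrier, stood at 5079 ± 1423 against 96.4 ± 37.9 CPM (log2 difference 5.84 ± 0.738, edgeR adjusted p = 0.000103), COL14A1 at 415 ± 201 against 14.5 ± 11.08, complement C3 at 358 ± 60.7 against 26.8 ± 28.0, and ANGPT1 at 51.8 ± 28.8 against 7.54 ± 8.18. MYOC was higher in the first (133 ± 92.8 against 41.4 ± 44.5 CPM, log2 difference 1.79 ± 0.409, edgeR adjusted p = 0.0119). The second cluster held more of MT3, a metallothionein (574 ± 24.5 against 6.16 ± 1.99 CPM, log2 difference -6.39 ± 0.565, edgeR adjusted p = 1.29e-06), CHRM2 (154 ± 19.97 against 25.8 ± 2.61), TPM1 (687 ± 60.6 against 234 ± 20.9) and the receptor ligand WNT5A (98.4 ± 35.5 against 32.7 ± 13.0). CYP1B1, LTBP2, LMX1B, PTGFR, CAV1 and NR3C1 did not pass the test.

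By list, 8 of 41 structural matrix genes were higher in the first cluster and 1, THBS1, lower. Complement had 2 of 10 higher (C3 and CFD) and 0 lower, and the glaucoma list 6 of 42 higher (ANGPT1, CAV2, COL11A1, EPDR1, MYOC and THSD7A) and 3 lower (ANKH, FBXO32 and LMO7). Drug targets had 3 of 14 higher (EDNRA, GUCY1A1 and PDE5A) and 1 lower (CHRM2), and contractility regulators 1 of 22 higher (SYNPO2) and 3 lower, among them CNN2 and TPM1. Adjusted over the list alone these were 9 and 3, 5 and 0, 6 and 4, 6 and 1, and 1 and 6. Matrix turnover had 3 of 19 higher and 0 lower, angiopoietin and VEGF signalling 2 of 14 and 1, and TGF-beta, BMP and WNT signalling 2 of 23 and 2. Ion and water transport had 1 of 14 and 1, phagocytosis 1 of 13 and 1, mechanosensing 0 of 12 and 2, antioxidant 0 of 17 and 1, and early response and mitochondrially encoded genes 0 either way. In camera's test the structural matrix (adjusted p = 1.19e-06), complement (0.00586) and drug targets (0.0249) stood higher and contractility regulators (0.00944) lower with the preset correlation, each with an adjusted p = 0.353 with an estimated correlation. THBS1, COL11A1, EPDR1, ANKH, CNN2 and FBXO32 were named after their values were seen. Over the 253 list genes 28 were higher and 16 lower, and over all 9268 genes 262 and 270. Without the animal as a block 11 and 6 list genes passed, and 14 of the 31 named genes past the threshold moved by over 1.5-fold when either animal was left out. In animal 6 alone and animal 9 alone the log2 difference was 1.18 and 4.73 for ANGPT1, 3.08 and 5.30 for C3, 2.64 and 1.44 for MYOC, and -0.79 and -2.35 for WNT5A.

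Blood vascular endothelial-like cells were compared with the other classes to place the vessels of the wedge. They carried the angiopoietin and VEGF receptors: TEK stood at 229 ± 50.9 CPM against 46.3 ± 9.56 in lymphatic or Schlemm canal endothelial-like cells, the next class, a log2 difference of 8.32 ± 0.48 from the mean of the classes (edgeR adjusted p = 6.77e-10). FLT1, a VEGF receptor, stood at 209 ± 17.4 against 5.19 ± 1.98 CPM, PTPRB, a phosphatase acting on TEK, at 290.2 ± 118 against 36.4 ± 42.2, and NOS3, the endothelial nitric oxide synthase, at 160.3 ± 14.7 against 0.844 ± 1.19 in macrophage-like cells. AQP1 reached 1816 ± 328 CPM against 336 ± 400.2 in lymphatic or Schlemm canal endothelial-like cells, and CAV1 1241 ± 253 against 1165 ± 251. Of 17 angiopoietin and VEGF signalling genes 11 were higher and 1, VEGFA, lower.

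Matrix turnover had 10 of 19 genes higher and 0 lower, with the plasminogen activator PLAT at 128 ± 18.9 CPM and PXDN at 43.7 ± 1.20. Phagocytosis and lysosome genes had 6 of 13 lower, such as the protease CTSL at 0.618 ± 0.874 CPM against 705 ± 78.9 in macrophage-like cells, and 1, GRN, higher. Drug targets had 5 of 15 higher, among them NOS3, GUCY1A1, GUCY1B1 and PTGER4, and 1 lower (PDE5A). Mechanosensing had 5 of 12 higher (CCN2, CRIM1, KLF2, PIEZO1 and WWTR1) and 1 lower (AJUBA). The glaucoma list had 10 of 42 higher and 2 lower (EFEMP1 and FBXO32), and the structural matrix 11 of 40 higher and 2 lower (EMILIN1 and THBS2). The difference of THBS2 reversed, to a log2 difference of 0.14, with all variable genes in the clustering, where 8 list genes were lower in place of 17. TGF-beta, BMP and WNT signalling had 5 of 23 higher and 2 lower, antioxidant genes 5 of 17 and 2, complement 3 of 10 and 0, ion and water transport 3 of 15 and 0, contractility 2 of 22 and 0, and early response 1 of 18 and 0. Mitochondrially encoded genes were higher for 10 of 13, and the median mitochondrial share of these cells was 15.03% in animal 6 and 11.2% in animal 9. In camera's test angiopoietin and VEGF signalling (adjusted p = 8.04e-15 with the preset correlation, 0.0556 with an estimated correlation), mitochondrially encoded genes (1.85e-05, 0.258), phagocytosis (0.00106, 0.128), matrix turnover (0.00265, 0.186), mechanosensing (0.0116, 0.128) and drug targets (0.034, 0.278) passed only with the preset one. Adjusted over the list alone, angiopoietin and VEGF signalling had 12 higher and 1 lower, matrix turnover 10 and 3, phagocytosis 1 and 9, drug targets 6 and 1, mechanosensing 5 and 1, the glaucoma list 12 and 2, the structural matrix 12 and 4, complement 4 and 1, antioxidant 5 and 3, and mitochondrially encoded genes 12 and 0, the other lists keeping their counts. AJUBA, CRIM1, EFEMP1, GRN, KLF2, PIEZO1, PTGER4 and VEGFA were named after their values were seen.

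Over all 9378 genes 1089 were higher and 266 lower by edgeR, in a fit that took classes with at least 10 cells per animal, chosen after seeing that animal 6 had 19 of these cells. MYOC passed the test here (log2 difference 2.79 ± 0.694, edgeR adjusted p = 0.00728), but all 43 of its UMIs came from 1 of 64 cells of animal 9 and the difference in animal 6 alone was -1.19. Of the 33 named genes past the threshold, 32 had the same sign in each animal alone, MYOC being the exception. The naming rule required the same sign of all but the genes always given, MYOC among them. Of the 33 genes, 10 moved by over 1.5-fold, such as AQP1 at 8.22 in animal 6 alone and 6.09 in animal 9 alone.

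Lymphatic or Schlemm canal endothelial-like cells were then set against blood vascular endothelial-like cells, as the outflow vessel shares lymphatic markers. The class was marked by CCL21 at 7571 ± 3517 CPM and PROX1 at 337 ± 150.4, and the blood class by ACKR1 at 1068 ± 17.3. LYVE1 and MMRN1 were also among the leading genes of the lymphatic or Schlemm canal class. Its marker list does not tell lymphatic vessels from Schlemm canal. The differences below can therefore not be credited to Schlemm canal. NOS3 was at least 35.7-fold lower in the lymphatic or Schlemm canal class, with 0 UMIs against 159. The apelin receptor APLNR (0 against 85 UMIs) and NRP1 (0 against 78 UMIs) were at least 19.1-fold and 17.5-fold lower, and VEGFC had 1 UMI against 229, a pooled ratio of 154 (counting interval 27.4 to 6130). TEK stood at 46.3 ± 9.56 against 229 ± 50.9 CPM (log2 difference -2.36 ± 0.591, edgeR adjusted p = 0.025), while its ligand ANGPT2 was higher, at 70.9 ± 25.7 against 14.6 ± 0.399 (log2 difference 2.48 ± 0.549, edgeR adjusted p = 0.00818). TGFB2 stood at 125 ± 10.1 against 11.6 ± 6.32 CPM, PDLIM3 at 202 ± 12.4 against 13.9 ± 0.475, and EPDR1 at 49.6 ± 23.6 against 5.42 ± 2.42. CFB, a complement factor, had 30 UMIs against 0 and was at least 14.8-fold higher, and the prostaglandin receptor PTGER2 had 53 against 2, a pooled ratio of 39.3 (counting interval 10.4 to 333).

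Angiopoietin and VEGF signalling had 1 of 17 genes higher (ANGPT2) and 6 lower, the structural matrix 3 of 40 higher (EMILIN1, NID1 and TNXB) and 6 lower, and matrix turnover 3 of 19 higher (TIMP4, MMP14 and TIMP2) and 2 lower (ADAMTS4 and CTSB). TGF-beta, BMP and WNT signalling had 3 of 23 higher (TGFB2, NBL1 and TGFB1) and 2 lower (BMP4 and SMAD7), and the glaucoma list 3 of 42 higher (ANGPT2, EPDR1 and MEIS1) and 2 lower (TEK and PLEKHA7). Drug targets had 1 of 15 higher (PTGER2) and 2 lower (NOS3 and PTGER4), and mitochondrially encoded genes 0 of 13 higher and 4 lower (ND2, ND4, ND4L and ND5). Complement had 1 of 10 higher (CFB) and 2 lower (C1R and CLU), contractility 1 of 22 higher (PDLIM3) and 1 lower (MYLK), and ion and water transport 0 of 15 higher and 1 lower (ATP1B1). Values were 0 and 1 for phagocytosis (ITGB5, of 13) and antioxidant genes (SOD2, of 17), early response had 2 of 18 higher (IER3 and HSPB1) and 0 lower, and mechanosensing had 0 of 12 either way. ND2, ND4, ND4L, ND5, HSPB1, SOD2, TNXB, TIMP2, CTSB, TGFB1 and MEIS1, which had 10 UMIs in animal 9 and 0 in animal 6, were named after their values were seen. CAV1 (1165 ± 251 against 1241 ± 253 CPM), NR3C1, CYP1B1 and EDNRB did not pass the test. Over all 9378 genes 251 were higher and 286 lower by edgeR. Camera passed angiopoietin and VEGF signalling (adjusted p = 0.0165 with the preset correlation, 0.364 with an estimated correlation) and mitochondrially encoded genes (2.48e-08, 0.364), both as lower. Adjusted over the list alone these had 3 and 7, and 0 and 12, higher and lower genes, the structural matrix 4 and 6, matrix turnover 6 and 2, TGF-beta, BMP and WNT signalling 3 and 2, the glaucoma list 3 and 2, drug targets 3 and 4, complement 2 and 3, and antioxidant 1 and 3. Without the animal as a block 8 list genes were higher in place of 17 and 14 lower in place of 25. All 30 named genes past the threshold had the same sign in each animal alone, with 15 moving by over 1.5-fold. The naming rule required the same sign of all but the genes always given. In animal 6 alone and animal 9 alone the log2 difference was -0.10 and -4.90 for PTGER4, 6.64 and 4.88 for CFB, 4.03 and 2.79 for TGFB2, and 2.06 and 3.84 for EPDR1.

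Ciliary muscle-like cells are named for the smooth muscle that pulls on the meshwork. Their leading genes held DES, MYH11 and CNN1 of its marker list, but also TNNC1 and TNNC2, troponin C genes of striated muscle. Whether striated muscle cells are in this class was not tested. The class could be set against pericyte-like cells only in animal 9, with 28 cells and 295232 UMIs against 56 cells and 433559 UMIs. There was thus no test, and the exact Poisson 95% intervals cover counting error only. Of 22 contractility regulators 6 were higher in ciliary muscle-like and 7 in pericyte-like cells, with overlapping intervals for 9. Higher in ciliary muscle-like cells were MYLK, at 2974 CPM (2780.0 to 3177) against 1093 (997 to 1196), and TPM1, at 9501 (9153 to 9859) against 5662 (5441 to 5891). Lower were CALD1, at 1741 (1594 to 1898) against 3453 (3280.0 to 3632), and TPM4, at 274 (218 to 341) against 1423 (1313 to 1540.0). FKBP5, a glucocorticoid-induced chaperone, stood at 420.0 CPM (349 to 501) against 73.8 (50.5 to 104). Pericyte-like cells held more of GUCY1B1, a subunit of the nitric oxide receptor, at 408 CPM (350.3 to 473) against 6.77 (0.82 to 24.5), of TGFB3, at 362 (308 to 423) against 6.77, and of ADAMTS4, at least 67.6-fold, with 298 UMIs against 0. Outside the mitochondrial list, intervals lay apart for 37 of 236 genes that were higher in ciliary muscle-like cells and for 77 that were higher in pericyte-like cells. The early response list held 4 of the former and 12 of the latter among 19 genes, with FOS at 2832 CPM against 7099, and the mitochondrially encoded list 10 and 0 among 13. No library replicates these values.

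The other classes were each compared with the mean of the rest. Pericyte-like cells, named for cells that wrap small vessels, held contractile transcripts, with 20 of 22 contractility regulators higher and 0 lower. TPM1 stood at 5199 ± 525 CPM against 663 ± 354 in pigment cell-like cells. MYLK stood at 1024 ± 73.2 CPM against 155 ± 40.6 in trabecular meshwork-like cells. The leading genes of this class held RGS5 of the pericyte markers, but also ACTA2, TAGLN and MYH11 of the ciliary muscle markers. The contractile transcripts can therefore not be credited to pericytes alone. Pericyte-like cells were also higher for 9 of 14 drug targets, such as the endothelin receptor EDNRA at 147 ± 9.45 CPM. Ciliary muscle-like cells, which were outside the fit, held more TPM1 and MYLK than pericyte-like cells in animal 9. Macrophage-like cells were higher for 11 of 13 phagocytosis and lysosome genes and lower for 2, with CTSL at 709 ± 79.5 CPM. Pigment cell-like cells were higher for 9 of 15 ion and water transport genes and lower for 2, with the potassium channel KCNJ13 at 691 ± 212 CPM against 6.45 ± 5.91 in pericyte-like cells, and higher for 7 of 13 phagocytosis genes. Stromal fibroblast-like cells were higher for 33 of 40 structural matrix, 15 of 19 matrix turnover, 7 of 10 complement and 8 of 12 mechanosensing genes. Non-myelinating Schwann-like cells were higher for 16 of 40 structural matrix genes, with MATN2 at 186 ± 1.505 CPM. Surface epithelial-like cells held PAX6 at 497 ± 249 CPM, and were lower for 21 of 40 structural matrix genes. T or NK cell-like cells were lower for 15 of 18 early response genes, and cycling cells for 18 of 40 structural matrix genes. Lymphatic or Schlemm canal endothelial-like cells were higher for 8 of 14 angiopoietin and VEGF signalling genes and lower for 2, with the Notch ligand DLL4 at 82.2 ± 13.1 CPM against 1.13 ± 1.60 in pericyte-like cells, in a fit without blood vascular endothelial-like cells. Against those, 1 of 17 genes of the list was higher and 6 lower.

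In camera's test these list differences passed with the preset and an estimated correlation for contractility (adjusted p = 1.81e-34 and 4.07e-04) and drug targets (3.39e-09 and 0.0150) in pericyte-like cells and for phagocytosis in macrophage-like cells (2.42e-06 and 0.0307). They also passed both for ion and water transport (1.13e-05 and 0.0348) and phagocytosis (6.21e-05 and 0.0348) in pigment cell-like cells, and in stromal fibroblast-like cells for structural matrix (8.84e-30 and 0.0208), matrix turnover (7.08e-13 and 0.0208), complement (1.28e-10 and 0.0272) and mechanosensing (7.10e-04 and 0.0299). The matrix difference of non-myelinating Schwann-like cells (adjusted p = 0.242 with an estimated correlation), those of surface epithelial-like (0.445) and cycling cells (0.481), the early response difference of T or NK cell-like cells (0.105) and the signalling difference of lymphatic or Schlemm canal endothelial-like cells (0.153) passed only with the preset one. Adjusted over the list alone the pericyte-like class had 21 higher contractility genes and 10 drug targets, the pigment cell-like class 10 transport genes, the stromal fibroblast-like class 35 matrix, 9 complement and 9 mechanosensing genes, the non-myelinating Schwann-like class 17 matrix genes, and the T or NK cell-like class 17 lower early response genes.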

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

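The test of scaling for the cells led by CCK, RSPO3 and CHGB was chosen only after the result was seen, while the other tests here were set before. MYOC stood above the limit that a count of 0 allows in 3 stromal clusters of animal 9 that have no name and lie outside the named classes. Cluster 19 is led by the same genes as the second stromal cluster compared there. It was at 77.0 CPM (exact Poisson 95% interval 70.8 to 83.6, 562 UMIs in 369 cells, limit 0.411 CPM) in cluster 19, at 579 CPM (526 to 636, 434 UMIs in 99 cells, limit 4.0) in cluster 21 and at 682 CPM (659 to 706, 3399 UMIs in 606 cells, limit 0.602) in cluster 23. Named trabecular meshwork-like clusters of animal 9 held 12.2 to 324 CPM. Unnamed cells held 4415 of the 4972 MYOC UMIs of animal 9 (88.8%) and trabecular meshwork-like cells 414 (8.33%), so most of that signal lies outside the named class.

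MYOC also passed the test in blood vascular endothelial-like cells, through 43 UMIs in animal 9. Free RNA from broken stromal cells would bring other abundant stromal transcripts along, but the median of observed over needed level was 0.14 over 10 such transcripts, which argues against free RNA. A few mixed or wrongly placed cells would hold most of the UMIs, and 100% of them lay in the 3 cells with the most, all in 1 cell that also held 174 UMIs of MGP, 88 of COL1A2 and 61 of DCN, and of the endothelial genes 11 of PECAM1, 12 of VWF and 5 of ACKR1. A mixed cell, holding stromal and endothelial transcripts, is therefore a candidate explanation, and no biological explanation was tested.

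Stromal cells led by CCK, RSPO3 and CHGB made up 0.507% of animal 6 (10 cells, exact 95% interval 0.243 to 0.930%) and 8.28% of animal 9 (369 cells, 7.49 to 9.13%). With genes scaled over both animals the shares were 1.77% (1.24 to 2.46%) and 8.46% (7.66 to 9.31%), which argues against scaling within each animal as the whole cause. With each cell thinned to 3000 UMIs as well, 171 and 342 shallower cells were left out. The shares were then 1.22% (0.767 to 1.84%) and 6.76% (6.01 to 7.57%), which argues against depth as the whole cause for the cells kept. These are shares of all cells rather than of stromal cells, and surface epithelial-like cells took 46.4% of animal 6 and 15.7% of animal 9. The larger epithelial part lowers every other share of animal 6, so part of each gap can come from it. With genes scaled over both animals nothing aligned the animals, so such cells of animal 6 could lie in other clusters, which was not tested. A difference in the tissue taken stays open and was not tested, nor was a biological explanation.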

How the results depend on the processing

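Counts of list genes past the threshold moved by over 1.5 times from the reported ones under these alternatives; the cause was not tested unless stated. For trabecular meshwork-like cells against the other classes, 10 lower genes became 19 with at least 1000 genes per cell, 17 with a mitochondrial share up to 10%, 17 with doublets kept and 20 with at least 50 cells per class. Against stromal fibroblast-like cells, 32 lower became 55 with no filter on low counts, where more genes were tested, and 40 higher became 21 with no replicate block, which drops the pairing of classes within an animal. For blood vascular endothelial-like cells against the other classes, 17 lower became 32 with no filter and 8 with all variable genes in the clustering. Between the endothelial classes, 17 higher became 29 with no filter and 8 with no block, and 25 lower became 14 with no block. For the 2 stromal clusters, 16 lower became 31 with no filter, 6 with no block and 10 with DESeq2, and 28 higher became 11 with no block.

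Reversed were THBS2 in blood vascular endothelial-like cells against the other classes, at a log2 difference of 0.14 with all variable genes in the clustering, and MYOC, from -1.19 without replicate 2 to 2.80 without replicate 1. Over the alternatives with a test, named genes kept their direction and side of the threshold in 589 values for trabecular meshwork-like cells against the other classes, with 7 newly past it. Against stromal fibroblast-like cells these were 603, 12 newly past and 15 no longer past, for blood vascular endothelial-like cells 483, 3 and 17, between the endothelial classes 454, 4 and 34, and for the stromal clusters 137, 2 and 29. Leaving out an animal leaves no residual degrees of freedom, so those are values with no test, clustering alternatives give no value for the stromal clusters, and a mitochondrial share up to 10% leaves too few blood vascular endothelial-like cells.

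Mean shares moved by over 1 SD as follows, in percent of cells. With a mitochondrial share up to 10%: blood vascular endothelial-like 0.361, ciliary muscle-like 0.753, stromal fibroblast-like 7.16, pigment cell-like 0.436, non-myelinating Schwann-like 0.934. With at least 1000 genes: lymphatic or Schlemm canal endothelial-like 1.15, Schwann-like 0.974, pigment cell-like 0.784, trabecular meshwork-like 19.8. Trabecular meshwork-like was 21.7 and unnamed 7.75 at resolution 0.5, trabecular meshwork-like 19.3 with all variable genes, Schwann-like 1.15 at resolution 2.0 and pigment cell-like 0.786 with doublets kept. Chosen only after the data were seen, trabecular meshwork-like was 20.1 and unnamed 8.11 with clusters kept despite their leading genes, and trabecular meshwork-like 23.9 with unresolved stromal clusters taken as trabecular. Blood vascular and lymphatic or Schlemm canal endothelial-like cells numbered 19 and 24 in animal 6. In simulated counts, with the change placed in the blood vascular class, their comparison recovered 28% of 4-fold higher genes.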

Other observations

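Every value here is outside the planned comparisons and no test was run. Transcripts of cell types from beside the wedge were looked for. Skeletal muscle ACTA1 had 0 UMIs in both animals, which allows a UMI in up to 0.152% of the cells of animal 6 and 0.0673% of those of animal 9. Of the other muscle genes, CKM had 5 and 23 UMIs in animal 6 and animal 9, TNNT3 8 and 40, and MYLPF 8 and 17. TNNC1 and TNNC2, among the leading genes of the ciliary muscle-like cluster, were not part of this search. Lens CRYGS stood at 0.592 and 1.01 CPM over all cells of animal 6 and animal 9, and fat cell ADIPOQ at 0.198 and 0.0948. Photoreceptor SAG stood at 2.21 CPM in animal 6 and 30.6 in animal 9, where 14.6% of cells had a UMI, and ROM1 had a UMI in 6.08% and 11.5% of cells. Hemoglobin HBB had a UMI in 26.1% and 26.5% of cells, at 22.1 and 72.3 CPM.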
